A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

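Expression was measured in 6 Saccharomyces cerevisiae samples with Affymetrix yeast arrays, 2 each after 1% DMSO, 200 nM rapamycin and 20 µM CID 3528206 for 3 hours. Per the labels, cultures of 10 mL were started at an OD600 of 0.05 and treated at 0.2, and 100 ng of total RNA was labelled with a 3' in vitro transcription kit. The deposited values are log2 RMA values, 1 per probe set, made by the authors with RMA, which corrects background, normalizes quantiles across arrays and summarises probes. The software, its version and its settings are not given in the sources used here, and the array scans are not used here. The deposited log2 values had column means from 6.937 to 6.943 over all probe sets, and the median of all probe sets was between 6.67 and 7.08.

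The table held 10928 probe sets, of which 213 were control or reporter probe sets, 1746 were for S. pombe, 1 named several genes and 3470 had no gene in the probe table. Gene names came from the probe table, and 12 symbols were updated through the reference annotation of assembly R64 of S. cerevisiae S288C, used for names only. The remaining 5498 probe sets named 1 S. cerevisiae gene each and gave 5449 genes. For the 47 genes with more than 1 probe set, the one with the highest mean over all arrays was used. Among the genes tested, 117 were measured by a probe set with the suffix _s_at or _x_at, which can hybridise more than 1 gene.

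Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays, with a mean per group and 3 residual degrees of freedom. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 over the 5449 genes of a comparison, and a log2 difference of at least 1 counted as 2-fold. Gene lists, 39 in all, were fixed from textbook knowledge before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives but 3. The genes deleted in BY4741 were not tested as a list. The other 38 lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists of the comparison. Estimated correlations between genes were far higher for ribosome biogenesis (0.426), cytosolic (0.427) and mitochondrial (0.457) ribosomal proteins, the respiratory chain (0.371) and histones (0.743). For such lists the camera p values at the preset may be much too small. Other lists lay near 0 or below it, such as nitrogen catabolite repression (-0.021). The named genes are, for each comparison, the 6 largest rises and the 6 largest falls among genes past the threshold for which the arrays of the 2 groups do not overlap, up to 2 members of each called list with the largest change in its direction, and a set of genes fixed in advance. Genes named only to account for a count of 5 or fewer were chosen after their values were seen and were not run through the alternatives.

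The similarity of the 2 treatments was measured by the correlation and covariance of the log2 differences and by the overlap of the calls. Both were set beside 100 simulations of unchanged groups that share the 2 DMSO arrays. The fit was tested on simulated data for each comparison with 200 genes changed. It called 82.1% of genes changed by 0.5 log2 units for rapamycin against DMSO, 85.1% for CID 3528206 against DMSO and 76.1% between the treatments. Of genes changed by 1 it called 100%, 100% and 98.5%, and 5.1%, 5.9% and 4.2% of its calls were genes left unchanged. The simulated noise was independent between arrays, with the same spread in all groups. In the data the difference between replicates had a standard deviation of 0.267 for CID 3528206, 0.123 for DMSO and 0.122 for rapamycin. Differences between replicates also correlated between groups, by 0.25 to 0.43. These rates may therefore be too favourable for the data, above all for comparisons with CID 3528206.

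Alternatives changed 1 choice at a time, 22 in all. They were leaving out each of the 6 arrays in turn, quantile normalization of the tested genes, centring each array on its median, filters on low values, all probe sets, probe sets that hybridise 1 gene only, the mean of the probe sets of a gene, the 4 arrays of a comparison alone, an adjusted p under 0.01, a variance prior with trend and robust fitting, the replicate number as a block, camera with an estimated correlation, fry in place of camera, and the difference between 3' and 5' control probe sets as a covariate. Leaving out an array of the group not compared gives the same fit as the 4 arrays of the comparison alone. For the similarity alone, each treatment was also set against its own DMSO array, in both assignments of the arrays. The covariate and these 2 fits were chosen after seeing the data. Fry tests a list against no change rather than against other genes, so ranges of adjusted p for lists leave it out. Groups of 2 are too small for a test of single arrays that stand apart, so none was made. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.089.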

Results

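Gene expression was measured on 6 Affymetrix arrays with biotin-labelled RNA from Saccharomyces cerevisiae cells labelled BY4741, a haploid laboratory strain. Cells growing in rich medium (YPD) received 1% DMSO, 200 nM rapamycin or 20 µM of a compound known by the code CID 3528206 for 3 hours, with 2 arrays in each of the 3 groups. Rapamycin inhibits TOR complex 1, a kinase complex that couples yeast growth to nutrient supply. The labels set the compound beside rapamycin, and the comparisons below ask how expression changed after each treatment and how far the changes resembled each other. The concentrations of rapamycin and the compound differ, and whether those cultures also held DMSO is not given in the sources used here. The labels call the arrays duplicates without saying whether they are separate cultures, so the p-values measure only the spread between these samples.

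On the log2 scale, the median of the 5449 genes tested lay between 10.08 and 10.11 in the 6 arrays. The 95th percentile of 1746 probe sets for Schizosaccharomyces pombe, a yeast not studied here, lay between 4.27 and 4.38 and served as the background. Of the genes tested, 98.6% had a mean above it, against 4.64% of the S. pombe probe sets. Across genes, replicate arrays correlated with r = 0.9981 for DMSO, 0.998 for rapamycin and 0.9906 for CID 3528206. The standard deviation of the difference between replicates was 0.123, 0.122 and 0.267 log2 units in the same order. CID 3528206 replicate 1 stood apart in the difference between 3' and 5' control probe sets, which averaged 1.69 log2 units over 7 yeast genes there and 0.91 to 1.14 in the other 5 arrays. The number of arrays, 2 per group, limits the precision. Errors after ± are standard errors of the log2 difference from limma with n = 2 arrays per group, and adjusted p values are limma or camera p values after Benjamini-Hochberg adjustment. The limma errors rest on a spread pooled over the 3 groups, although that of the CID 3528206 replicates was wider.

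**Figure D1:**
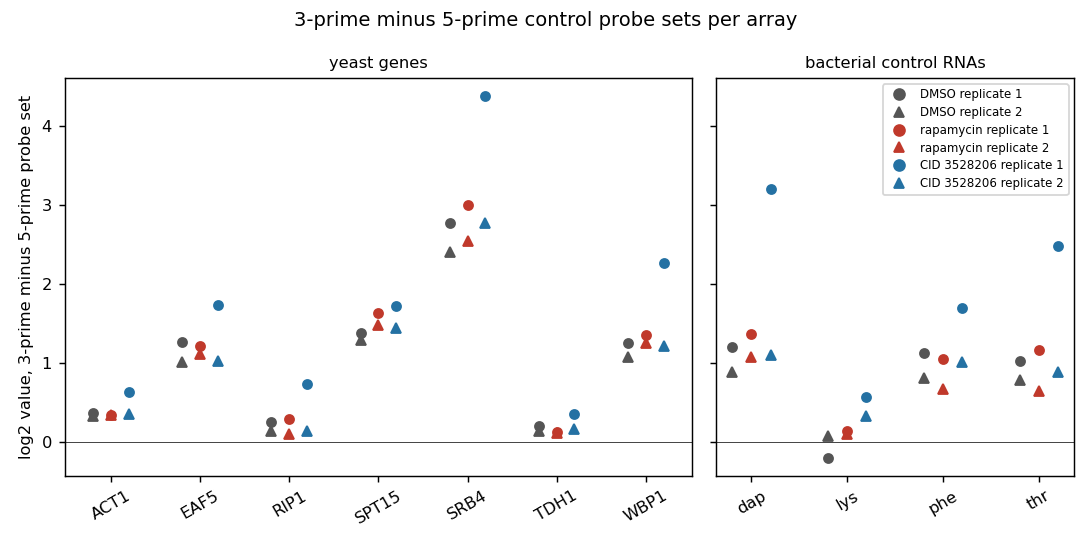
Difference between the 3' and 5' control probe sets (log2 units) of 7 yeast genes and 4 bacterial control RNAs in each of the 6 arrays, 1 point per control RNA. The mean of the bacterial RNAs was 1.99 in CID 3528206 replicate 1 and between 0.62 and 0.93 in the other 5 arrays.

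The genes deleted in BY4741 gave signal far above background in all 6 arrays. LEU2, URA3, MET17 and HIS3, whose products make leucine, uracil, methionine and histidine, had levels from 10.39 to 12.11, where the highest 99th percentile of the S. pombe probe sets was 5.24. The 5 genes measured from the alpha and diploid cell list are genes of alpha cells. They lay between 8.59 and 13.47, among them the a-factor receptor gene STE3 and the pheromone gene MF(ALPHA)1. The 7 genes of a cells, the mating type of BY4741, lay between 4.89 (AGA2, DMSO replicate 2) and 8.24 (STE2, rapamycin replicate 2). In both DMSO arrays every alpha cell gene and every deleted gene lay at 10.9 or above. The strain is given here only as the label states it.

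**Figure D2:**
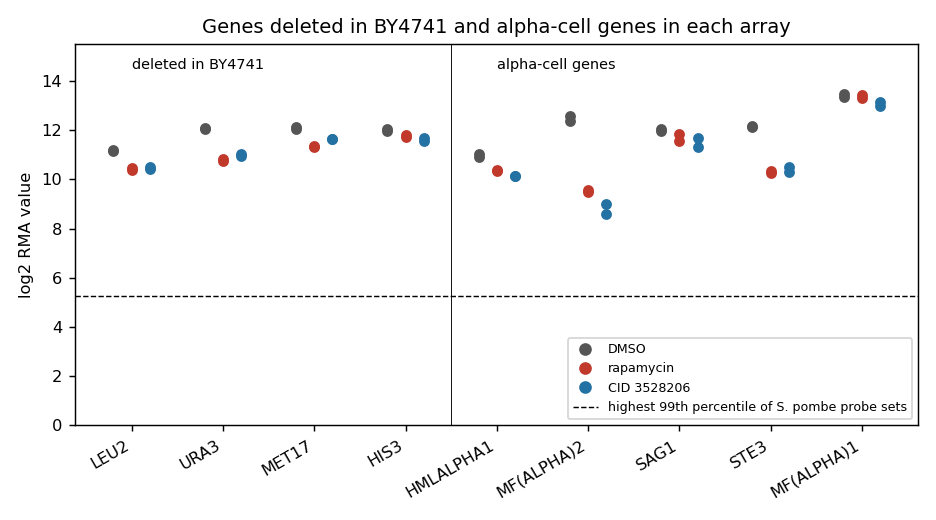
Level (log2) of the 4 genes deleted in BY4741 and of the alpha-cell genes in each of the 6 arrays, 1 point per array, with a line at the highest 99th percentile of the S. pombe probe sets (5.24). The points of every gene lie above the line, with the lowest at 8.59.

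After rapamycin, genes for the uptake and use of poorer nitrogen sources showed the largest rises. MEP2, a high-affinity ammonium permease, rose 51.1-fold (log2 difference 5.68 ± 0.07, limma adjusted p = 1.08e-06). DAL3 of allantoin breakdown rose 35.4-fold, the general amino acid permease gene GAP1 34.4-fold and GDH3, a glutamate dehydrogenase, 32.1-fold. The urea transporter gene DUR3 rose 31.6-fold and DAL80, a repressor of nitrogen genes, 25.9-fold. Both rapamycin arrays lay above both DMSO arrays for these 6 genes, with standard errors from 0.07 to 0.16 log2 units and limma adjusted p up to 1.46e-05. Of 39 measured genes of nitrogen catabolite repression, the programme kept off by good nitrogen sources, 32 rose, 2 (RSB1 and OPT2) fell and 5 did not pass the test, with 32 up and 3 down adjusted over the list alone. That list shifted upward (camera adjusted p = 1.7e-12, and adjusted p = 0.119 with an estimated correlation). Among 25 amino acid permeases, 16 rose, 7 fell and 2 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.46 with an estimated correlation). The proline permease gene PUT4 rose 11.5-fold (3.52 ± 0.07), and 6 of the 25 permeases are also in the nitrogen list. Of 38 components of the TOR pathway, 21 rose, 2 (VAM6 and MEH1) fell and 15 did not pass, with 21 and 2 adjusted over the list alone (camera adjusted p = 0.000588, and adjusted p = 0.258 with an estimated correlation). The GATA activator gene GAT1 rose by 2.27 ± 0.17 and the kinase gene NPR1 by 1.55 ± 0.08, while the difference for TOR1 was 0.17 ± 0.10 (limma adjusted p = 0.203). FPR1, which encodes the rapamycin-binding protein, is not analysed here.

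Genes for the use of carbon sources other than glucose rose as well. Of 20 genes of gluconeogenesis and the glyoxylate cycle, 19 rose, 0 fell and 1 (MDH3) did not pass, and 19 rose adjusted over the list alone (camera adjusted p = 1.55e-11, and adjusted p = 0.258 with an estimated correlation). The carnitine carrier gene CRC1 rose 23.1-fold (4.53 ± 0.12) and the acetate transporter gene ADY2 20.6-fold (4.36 ± 0.12). In the TCA cycle list of 20 genes, 13 rose, 0 fell and 7 did not pass, and 13 rose adjusted over the list alone (camera adjusted p = 0.000141, and adjusted p = 0.258 with an estimated correlation). The citrate synthase gene CIT3 rose by 3.04 ± 0.12 and the pyruvate carboxylase gene PYC1 by 2.52 ± 0.10. Of 41 genes of the respiratory chain and ATP synthase, 32 rose, 3 (CYC7, NDE1 and CYC1) fell and 6 did not pass, with 33 up and 3 down adjusted over the list alone (camera adjusted p = 7.7e-07, and adjusted p = 0.46 with an estimated correlation). NDE2, an NADH dehydrogenase, rose by 2.32 ± 0.09 and the succinate dehydrogenase gene SDH2 by 1.01 ± 0.11. Of 15 vacuolar hydrolases, 10 rose, 0 fell and 5 did not pass, with 11 up adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.398 with an estimated correlation). The mannosidase gene AMS1 rose by 2.45 ± 0.11 and the carboxypeptidase gene CPS1 by 2.01 ± 0.11. CIT2, the citrate synthase of the retrograde response, rose by 1.83 ± 0.07 (limma adjusted p = 1.8e-05). Of the 14 genes of that list 7 rose, 1 (PXA1) fell and 6 did not pass, with 7 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0701).

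Lists of the translation apparatus other than ribosome biogenesis shifted downward, with small differences per gene. Most cytosolic ribosomal protein genes fell, while most members of the others did not pass or rose. Of 128 cytosolic ribosomal protein genes, 0 rose, 101 fell and 27 did not pass, and 104 fell adjusted over the list alone (camera adjusted p = 2.56e-15, and adjusted p = 0.46 with an estimated correlation). RPL9A fell 2.32-fold (-1.21 ± 0.08) and RPS14B 1.95-fold (-0.96 ± 0.12), while RPL3 differed by -0.16 ± 0.07 and did not pass. Of 72 mitochondrial ribosomal protein genes, 2 (RSM22 and MRPL10) rose, 32 fell and 38 did not pass, with 1 up and 31 down adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.728 with an estimated correlation). MRPL19 fell by 0.87 and MNP1 by 0.63 on the log2 scale. In the list of 34 translation factors, 2 (GCD6 and CAM1) rose, 15 fell and 17 did not pass, with the same 2 counts, 2 and 15, adjusted over the list alone (camera adjusted p = 0.00809, and adjusted p = 0.258 with an estimated correlation). The initiation factor gene GCD7 and the elongation factor gene TEF4 fell by 0.63 and 0.62. Of 19 aminoacyl-tRNA synthetases, 0 rose, 9 fell and 10 did not pass, with 9 down adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.503 with an estimated correlation). GLN4 fell by 0.84 ± 0.12, and the call for this list ended without rapamycin replicate 2 (adjusted p = 0.0681, range 0.0161 to 0.503 over the alternatives). It also ended after quantile normalization of the tested genes (0.108) and without the third of genes with the lowest mean (0.0512). CDC60 fell by 0.49 ± 0.13, a call that ended without any single DMSO or rapamycin array (highest adjusted p = 0.114 without rapamycin replicate 2, range 0.000238 to 0.114). The ribosome biogenesis list shifted upward, with 45 of 131 genes up, 9 down and 77 not past the test, and with 39 up and 5 down adjusted over the list alone (camera adjusted p = 0.00567, and adjusted p = 0.79 with an estimated correlation). The ribosome assembly genes RPF1 and DBP7 rose by 1.09 ± 0.09 and 0.94 ± 0.07, and the nucleolar protein gene NSR1 rose by 0.51 ± 0.09. NOP1, which encodes fibrillarin, fell by 0.39 ± 0.10, a call that ended without any single DMSO or rapamycin array (highest adjusted p = 0.109 without DMSO replicate 2, range 0.00112 to 0.109 over the alternatives).

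The largest falls after rapamycin were in genes of several kinds. The open reading frame YOL014W fell 23.6-fold (-4.56 ± 0.13, limma adjusted p = 6.56e-06) and YDL241W 12.2-fold. GCV1 of the glycine cleavage system fell 12.1-fold, the glycogen synthase gene GSY1 10.9-fold, MTD1 of folate metabolism 8.56-fold and the alpha-factor gene MF(ALPHA)2 7.72-fold, with limma adjusted p up to 6.66e-05. Of 38 G1/S cell cycle genes, 3 (IRR1, PCL2 and CLN1) rose, 19 fell and 16 did not pass, with 3 up and 22 down adjusted over the list alone (camera adjusted p = 0.00761, and adjusted p = 0.258 with an estimated correlation). TOS4, a regulator of G1/S genes, and the DNA ligase gene CDC9 fell by 1.29 ± 0.07 and 1.15 ± 0.07. That list did not pass without the third of genes with the lowest mean (adjusted p = 0.174, range 0.00185 to 0.258 over the alternatives). Of 24 unfolded protein response genes, 2 (ERO1 and YET1) rose, 13 fell and 9 did not pass, as they did adjusted over the list alone, with 2 and 13 (camera adjusted p = 0.00727, and adjusted p = 0.414 with an estimated correlation). ALG7 of protein glycosylation fell by 1.08 ± 0.08 and the disulfide isomerase gene MPD1 by 0.88 ± 0.08. Of 28 cell wall integrity genes, 14 rose, 6 fell and 8 did not pass, with 14 and 6 adjusted over the list alone (camera adjusted p = 0.0358, and adjusted p = 0.36 with an estimated correlation). The wall protein gene PIR3 rose by 2.68 ± 0.17 and the kinase gene KDX1 by 1.78 ± 0.10, and the call for the list ended without rapamycin replicate 1 (adjusted p = 0.0585, range 0.00222 to 0.36 over the alternatives).

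Mating and sporulation genes changed too after rapamycin. Of 5 alpha cell genes, 0 rose, 3 (MF(ALPHA)2, STE3 and HMLALPHA1) fell and 2 did not pass the test, with 3 down adjusted over the list alone (camera adjusted p = 0.0207, and adjusted p = 0.46 with an estimated correlation). MF(ALPHA)2 is named above, and STE3 fell by 1.84 ± 0.09. Of 7 a cell genes, 4 (MFA2, STE2, AGA2 and MFA1) rose and 3 did not pass, and 4 rose adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.46 with an estimated correlation). The a-factor gene MFA2 rose by 1.28 ± 0.15 and the alpha-factor receptor gene STE2 by 1.09 ± 0.10. Of 26 pheromone response genes, 13 rose, 3 (FAR1, SST2 and FUS1) fell and 10 did not pass, with 13 up and 4 down adjusted over the list alone (camera adjusted p = 0.0216, and adjusted p = 0.335 with an estimated correlation). PRM5 rose by 1.05 ± 0.07, and STE2 and 3 other genes are also in the a cell list. Of 37 sporulation and meiosis genes, 15 rose, 5 (ZIP1, DMC1, IME1, SPO16 and SSP1) fell and 17 did not pass, with 15 and 5 adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.46 with an estimated correlation). The spore wall gene SPS100 rose by 1.98 ± 0.13 and the meiotic activator gene NDT80 by 1.35 ± 0.07. Quantile normalization of the tested genes took the list mean from 0.336 to 0.028 for sporulation. It went from 0.297 to 0.137 for the pheromone list and from 0.713 to 0.401 for the a cell list. The call for sporulation ended without rapamycin replicate 2 (adjusted p = 0.0681), without genes under the background (0.0519) and with the covariate added later (0.0534), and that for the pheromone list without the third of genes with the lowest mean (0.0924). After quantile normalization of the tested genes, adjusted p was 0.147 for the pheromone list, 0.128 for the a cell list and 0.812 for sporulation, with ranges over the alternatives of 0.000973 to 0.335, 0.000467 to 0.46 and 0.0011 to 0.812.

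Among genes fixed in advance for inspection, HSP12, a small membrane stress protein, rose 3.54-fold (1.82 ± 0.22). The general stress response list did not pass after rapamycin: of 66 genes 24 rose, 25 fell and 17 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.719). The autophagy gene ATG8 rose by 0.59 ± 0.12 and the vacuolar aminopeptidase gene APE1 by 0.34 ± 0.10. The catalase gene CTT1 fell by 0.38 ± 0.11, the G1 cyclin gene CLN2 by 0.37 ± 0.08 and the drug pump gene PDR5 by 0.53 ± 0.08. The call for ATG8 ended without DMSO replicate 1 or rapamycin replicate 1, those for CTT1 and CLN2 without either DMSO array or rapamycin replicate 1, and that for APE1 without any single DMSO or rapamycin array. The highest adjusted p was 0.0555 for ATG8, 0.176 for CTT1 and 0.0839 for CLN2 without rapamycin replicate 1, and 0.164 for APE1 without DMSO replicate 2. Over the alternatives their adjusted p ranged from 0.000176 to 0.0555, 0.0151 to 0.176, 0.00115 to 0.0839 and 0.00145 to 0.164. With all probe sets tested the calls for CTT1 and APE1 ended too (0.0651 and 0.072). Of the genes deleted in BY4741, LEU2 fell by 0.75 ± 0.07, URA3 fell by 1.29 ± 0.07 and MET17 fell by 0.76 ± 0.07, while HIS3 differed by -0.23 ± 0.08 and did not pass.

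In all, limma called 2873 of 5449 genes after rapamycin, 1446 higher and 1427 lower than after DMSO. At least 2-fold changes were called for 461 genes, 326 higher and 135 lower. The 2 rapamycin and 2 DMSO arrays did not overlap for any of the 2873, as for 4626 of all genes tested, where chance alone gives 33.3%. Camera called 19 of 38 lists, 12 up and 7 down. Lists called in another comparison but not after rapamycin were the retrograde and general stress responses, autophagy, the proteasome, hexose transporters, the multidrug and iron regulons, chaperones, ergosterol synthesis, histones, G2/M and M/G1 (camera adjusted p 0.0701 to 0.948). Without DMSO replicate 1 or 2, or rapamycin replicate 1 or 2, the count of changed genes was 1806, 1820, 1794 and 1815, and without the third of genes with the lowest mean the 2-fold count was 263. No list call in any comparison held with an estimated correlation, with 6, 3 and 4 lists at an unadjusted p under 0.05 for rapamycin, the compound and their difference, and 26, 28 and 21 lists called by fry. Fry tests a list against no change, not against other genes, and did not call mitochondrial ribosomal proteins (0.0572) or ribosome biogenesis (0.114) after rapamycin.

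After CID 3528206, the largest rises included genes for poorer nitrogen sources and the carnitine genes CRC1 and YAT2. MEP2 rose 40.4-fold (5.34 ± 0.07, limma adjusted p = 1.58e-06), GDH3 22.0-fold and DAL3 21.3-fold. CRC1 rose 19.9-fold and YAT2, a carnitine acetyltransferase, 17.5-fold, and NCA3, linked to mitochondrial function, rose 17.0-fold, with limma adjusted p up to 9.05e-06. Of the 39 genes of nitrogen catabolite repression, 29 rose, 2 (YHI9 and DCG1) fell and 8 did not pass, with 29 up and 2 down adjusted over the list alone (camera adjusted p = 2.17e-11, and adjusted p = 0.131 with an estimated correlation). GAP1 rose by 3.90 ± 0.08 and DAL80 5.67-fold (2.50 ± 0.16). Of 25 amino acid permeases, 16 rose, 4 (MUP3, MMP1, MUP1 and BAP2) fell and 5 did not pass, with 16 and 4 adjusted over the list alone (camera adjusted p = 0.00187, and adjusted p = 0.459 with an estimated correlation). The GABA permease gene UGA4 rose by 2.62 ± 0.08. Of 38 TOR pathway components, 21 rose, 1 (MEH1) fell and 16 did not pass, with 21 and 1 adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.428 with an estimated correlation). GAT1 rose by 1.84 ± 0.17 and NPR1 by 1.12 ± 0.08, while TOR1 differed by 0.10 ± 0.10 and did not pass.

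Lists of gluconeogenesis, the TCA cycle, vacuolar hydrolases and the iron regulon shifted upward after the compound, as did those of the respiratory chain and the retrograde response in calls that depended on single arrays. Of 20 genes of gluconeogenesis and the glyoxylate cycle, 19 rose, 1 (MDH3) fell and 0 did not pass, with 19 and 1 adjusted over the list alone (camera adjusted p = 9.54e-09, and adjusted p = 0.428 with an estimated correlation). ADY2 rose 7.13-fold (2.83 ± 0.12). Of 20 TCA cycle genes, 12 rose, 0 fell and 8 did not pass, with 12 up adjusted over the list alone (camera adjusted p = 0.00312, and adjusted p = 0.428 with an estimated correlation). CIT3 rose by 2.80 ± 0.12 and PYC1 by 2.51 ± 0.10. Of 15 vacuolar hydrolases, 9 rose, 0 fell and 6 did not pass, with 10 up adjusted over the list alone (camera adjusted p = 0.00503, and adjusted p = 0.459 with an estimated correlation). CPS1 rose by 1.91 ± 0.11 and AMS1 by 1.74 ± 0.11. Of 41 genes of the respiratory chain and ATP synthase, 16 rose, 6 fell and 19 did not pass, with 16 and 6 adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.709 with an estimated correlation). That call ended without either DMSO array (adjusted p = 0.114 and 0.0597), either rapamycin array (0.0595) or CID 3528206 replicate 2, where the mean of the list went from 0.15 to 0.08 (0.349). It also ended with the 4 arrays alone (0.0595) and without the third of genes with the lowest mean (0.0533, range 0.00284 to 0.709 over the alternatives). NDE2 rose by 1.80 ± 0.09 and QCR9 of complex III by 0.50 ± 0.07. Of 14 genes of the retrograde response, which links mitochondria to the nucleus, 7 rose, 1 (PXA1) fell and 6 did not pass, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.457 with an estimated correlation). The retrograde call ended without CID 3528206 replicate 1 or 2 (adjusted p = 0.0583 and 0.0912) and with the replicate number as a block (0.0535, range 0.00303 to 0.457). The mean of this list was 0.51, against 0.53 after rapamycin, and 0 of its genes differed between the treatments. DLD3 rose by 1.91 ± 0.08 and CIT2 by 1.72 ± 0.07. Of 34 iron regulon genes, 22 rose, 5 (ENB1, FRE2, FRE4, MRS4 and FRE5) fell and 7 did not pass, with 22 and 5 adjusted over the list alone (camera adjusted p = 0.000941, and adjusted p = 0.428 with an estimated correlation). The heme oxygenase gene HMX1 rose 8.84-fold (3.14 ± 0.15) and the siderophore transporter gene ARN1 2.81-fold (1.49 ± 0.09).

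Ribosome and proteasome lists shifted by small amounts after the compound, and those of translation factors and aminoacyl-tRNA synthetases did not pass (camera adjusted p = 0.185 and 0.79). Of 72 mitochondrial ribosomal protein genes, 0 rose, 50 fell and 22 did not pass, with 54 down adjusted over the list alone (camera adjusted p = 1.13e-09, and adjusted p = 0.515 with an estimated correlation). MRPL19 fell 2.11-fold (-1.07 ± 0.09) and MRPL20 fell by 0.76 ± 0.08. Of 128 cytosolic ribosomal protein genes, 1 (RPL9B) rose, 31 fell and 96 did not pass, and 0 passed adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.543 with an estimated correlation). RPS9A and RPS14B fell by 0.63 ± 0.15 and 0.56 ± 0.12, calls that ended without DMSO replicate 2 (adjusted p = 0.0732 and 0.0726), for RPS9A also without DMSO replicate 1 (0.0658, ranges 0.000365 to 0.0732 and 0.00121 to 0.0726 over the alternatives), and RPL3 differed by -0.01 ± 0.07. In the ribosome biogenesis list, 41 of 131 genes rose, 4 (UTP30, SPB4, NOP10 and NHP2) fell and 86 did not pass, with 27 and 2 adjusted over the list alone (camera adjusted p = 0.0407, and adjusted p = 0.814 with an estimated correlation). The call for this list ended without CID 3528206 replicate 2 or DMSO replicate 1 (adjusted p = 0.83 and 0.288, range 0.000136 to 0.83). RRP12 of small-subunit processing rose by 0.75 ± 0.08 and DBP7 by 0.64 ± 0.07, while NOP1 differed by -0.28 ± 0.10 and did not pass. NSR1 rose by 0.31 ± 0.09, a call that ended without any single DMSO or rapamycin array (highest adjusted p = 0.168 without DMSO replicate 1, range 0.0066 to 0.168 over the alternatives), with the 4 arrays alone (0.0607) and with all probe sets tested (0.0707). Of 37 proteasome genes, 1 (RPN4, a transcription factor for the others) rose, 9 fell and 27 did not pass, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.543 with an estimated correlation). RPN13 and RPN3 fell by 0.46 ± 0.10 and 0.40 ± 0.10, calls that ended without DMSO replicate 2 (adjusted p = 0.0667 and 0.0988) or DMSO replicate 1 (0.0505 and 0.0619, ranges 0.00146 to 0.0667 and 0.00141 to 0.0988 over the alternatives). Of 9 histone genes, 0 rose, 7 fell and 2 did not pass, with 8 down adjusted over the list alone (camera adjusted p = 0.00383, and adjusted p = 0.522 with an estimated correlation). The variant histone gene HTZ1 and the linker histone gene HHO1 fell by 0.83 ± 0.07 and 0.83 ± 0.08.

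The largest falls after the compound were of MF(ALPHA)2 (12.7-fold, -3.67 ± 0.15, limma adjusted p = 3.21e-05) and EGO4 (12.4-fold). GCV1 fell 11.4-fold, GSY1 11.1-fold, YOL014W 7.83-fold and RGI1, named for respiratory growth, 6.16-fold, with limma adjusted p up to 9.51e-05. Of 66 genes of the general stress response, 12 rose, 36 fell and 18 did not pass, with 13 up and 36 down adjusted over the list alone (camera adjusted p = 0.00197, and adjusted p = 0.515 with an estimated correlation). GSY1 is in this list, and the glycerol synthesis gene GPD1 fell by 1.77 ± 0.08. CTT1 fell by 0.88 ± 0.11, while HSP12 differed by -0.09 ± 0.22 and did not pass. Of 28 cell wall integrity genes, 15 rose, 4 (PIR5, CWP1, SPI1 and PIR1) fell and 9 did not pass, with 16 up and 4 down adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.428 with an estimated correlation). PIR3 rose by 2.35 ± 0.17 and GSC2, a glucan synthase, by 1.91 ± 0.09.

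Of the 5 alpha cell genes (those above with SAG1 and MF(ALPHA)1), 0 rose, 5 fell and 0 did not pass, with 5 down adjusted over the list alone (camera adjusted p = 0.00317, and adjusted p = 0.457 with an estimated correlation). STE3 fell by 1.75 ± 0.09 after CID 3528206. Of 7 a cell genes, 5 (MFA2, STE2, AGA2, MFA1 and STE6) rose and 2 did not pass, with 7 up adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.515 with an estimated correlation). MFA2 rose by 1.03 ± 0.15 and STE2 by 0.67 ± 0.10. Of 37 sporulation and meiosis genes, 17 rose, 4 (DMC1, SPO11, SSP1 and ZIP1) fell and 16 did not pass, with 17 and 4 adjusted over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.515 with an estimated correlation). After quantile normalization of the tested genes, adjusted p was 0.375 for sporulation and 0.104 for the a cell list, with ranges of 0.000291 to 0.515 and 0.000597 to 0.515. The list means went with it from 0.359 to 0.115 for sporulation and from 0.541 to 0.287 for the a cell list. SPS100 rose by 1.70 ± 0.14 and the spore wall gene DIT1 by 1.60 ± 0.10. Among the genes fixed in advance, CLN2 fell by 0.40 ± 0.08, a call that ended without DMSO replicate 2 (adjusted p = 0.0695, range 0.00208 to 0.0695 over the alternatives), and ATG8, APE1 and PDR5 differed by -0.12 ± 0.12, -0.01 ± 0.10 and 0.18 ± 0.08 and did not pass. LEU2 fell by 0.70 ± 0.07, URA3 fell by 1.08 ± 0.07, MET17 fell by 0.45 ± 0.07 and HIS3 fell by 0.40 ± 0.08. The call for HIS3 ended without DMSO replicate 2 (adjusted p = 0.0717, range 0.00235 to 0.0717).

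For CID 3528206 limma called 2752 genes, 1424 higher and 1328 lower than after DMSO, and 385 at least 2-fold, 273 higher and 112 lower. The arrays of the 2 groups did not overlap for any of the 2752, as for 4128 of the 5449 genes tested, where chance gives 33.3%. Camera called 19 of 38 lists, 13 up and 6 down. Not called here, but in another comparison, were translation factors, tRNA synthetases, autophagy, hexose transporters, the multidrug regulon, chaperones, the unfolded protein response, ergosterol synthesis, G1/S, G2/M, M/G1 and the pheromone response (camera adjusted p 0.0844 to 0.79). Without DMSO replicate 1 and 2 the count of changed genes was 1715 and 1553, and the 2-fold count was 224 without the third of genes with the lowest mean.

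**Figure D3:**
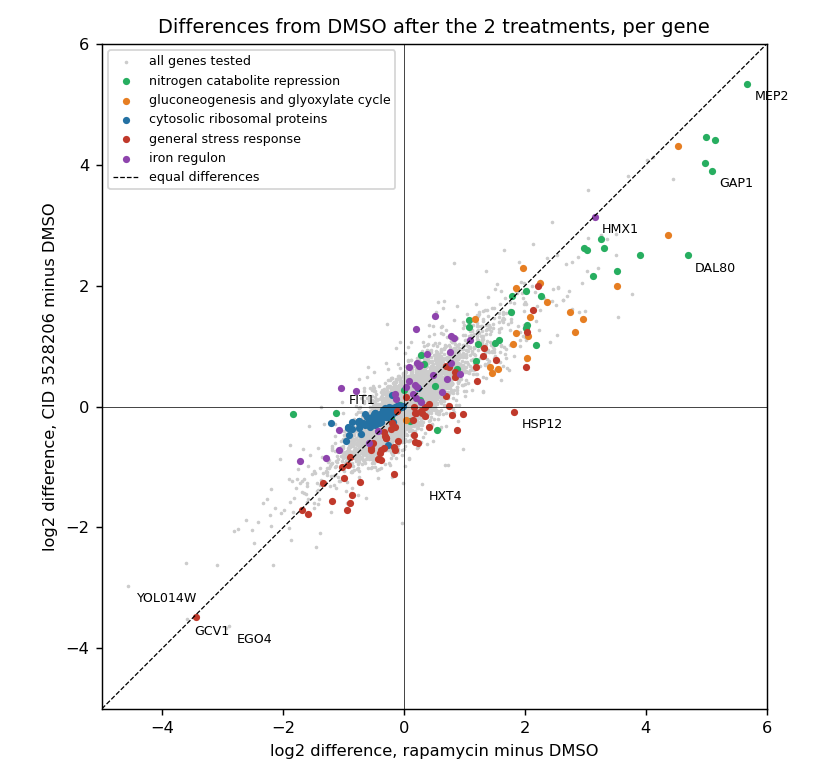
Log2 difference from DMSO after rapamycin (horizontal axis) against that after CID 3528206 (vertical axis), 1 point per gene for 5449 genes, with 5 gene lists in colour and a dashed line at equal differences. The points follow a rising band with r = 0.878 and a slope of 0.783.

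Log2 differences after the 2 treatments were similar across genes. Pearson r was 0.878 and Spearman rho 0.811 over 5449 genes, which are not independent replicates, with r = 0.818 without CID 3528206 replicate 2. Both differences share the 2 DMSO arrays, and 100 simulated pairs of unchanged groups that shared them gave a mean r of 0.5 and at most 0.536. The simulations drew the noise of each array independently. In the data, differences between replicates correlated by 0.25, 0.43 and 0.32 between pairs of groups. Simulated r and overlaps, here and below, may therefore be too low for these arrays. Covariance of the differences was 0.347, against 0.00615 in the simulations. The slope of the compound on rapamycin was 0.783. Of 461 genes changed at least 2-fold by rapamycin, 438 changed the same way after the compound and 1 the opposite way, and the median ratio of their log2 differences, compound over rapamycin, was 0.796. Overall 2037 genes changed in the same direction after both treatments, 1087 up and 950 down, where independent lists would share 726 and simulated unchanged groups at most 1. In opposite directions changed 33 genes, where independent lists would share 725. Among those 33 are HXT4, a hexose transporter gene (0.30 ± 0.07 after rapamycin and -1.27 ± 0.07 after the compound), and FIT1, a cell wall protein gene of iron uptake (-1.04 ± 0.09 and 0.30 ± 0.09). Without DMSO replicate 1 or 2 the same-direction count was 1229 and 1171. With a separate DMSO array as the control of each treatment, a fit added after the data were seen, r was 0.844 and 0.877 for the 2 ways to assign the arrays, where simulated unchanged groups gave at most 0.07. In these fits 1169 and 1158 genes changed in the same direction, where independent lists would share 289.5 and 260.3.

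**Figure D4:**
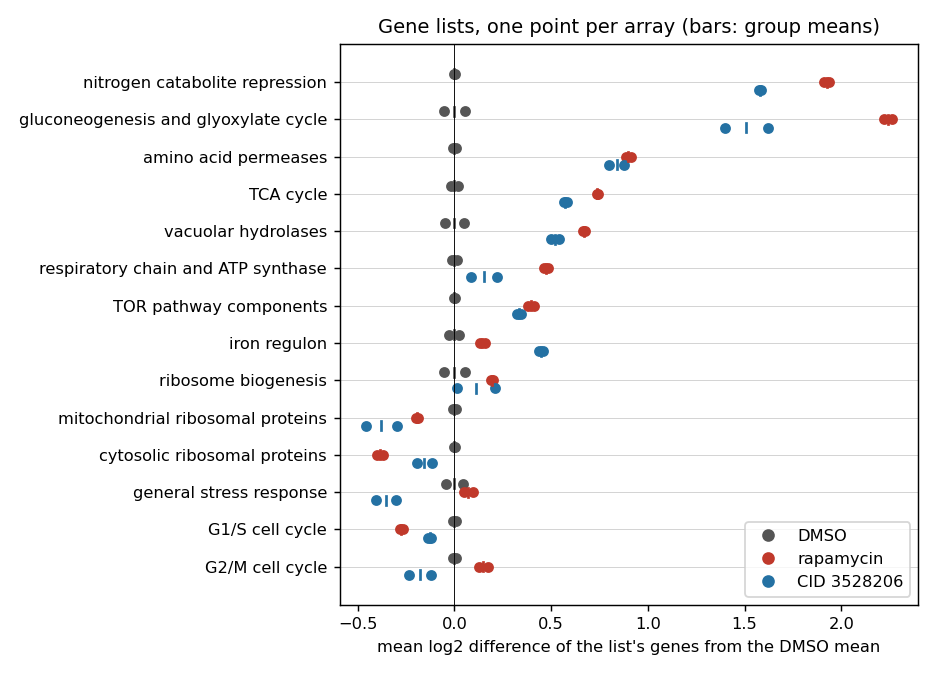
Mean log2 difference from the DMSO mean of 14 gene lists in each of the 6 arrays, 1 point per array. Nitrogen catabolite repression lies at 1.91 and 1.94 in the rapamycin arrays and at 1.58 and 1.57 in those of CID 3528206.

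Set directly against rapamycin, CID 3528206 gave lower levels of a set of nitrogen, carbon and stress genes. DAL80 was 4.57-fold lower (-2.19 ± 0.16, limma adjusted p = 0.00259), RGI2, named for respiratory growth, 4.17-fold lower and HXT7 3.68-fold lower. HXT7 is measured by a probe set that can hybridise closely related genes. HSP12 was 3.75-fold lower, YKR075C 3.73-fold lower and TMA10, a stress gene, 3.21-fold lower. RSB1, a transporter of sphingoid bases, was 3.30-fold higher (1.72 ± 0.12), IML2 3.14-fold, YOL014W 3.01-fold, YMR317W 2.94-fold, the sterol esterification gene ARE2 2.59-fold and FIT1 2.53-fold higher, with limma adjusted p up to 0.00432. Calls for HSP12 and YKR075C ended without rapamycin replicate 2 (adjusted p = 0.0517 and 0.0832), for YKR075C also without rapamycin replicate 1 (0.0714, ranges 0.00102 to 0.0517 and 0.000876 to 0.0832 over the alternatives). CID 3528206 replicate 1, with its larger difference between 3' and 5' control probe sets, belongs to this comparison. Of the genes fixed in advance, RPL3, NOP1, NSR1, APE1, CLN2, TOR1, LEU2, URA3 and HIS3 did not pass, with differences from -0.36 (APE1) to 0.22 (URA3). MET17 was higher by 0.32 ± 0.07, a call that ended without any single DMSO or rapamycin array (highest adjusted p = 0.178 without rapamycin replicate 1, range 0.0106 to 0.178).

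Several nitrogen and carbon lists were lower after the compound than after rapamycin. The amino acid permeases, with 5 of 25 genes higher and 6 lower, and the TCA cycle, with 0 of 20 higher and 6 lower, did not pass (camera adjusted p = 0.826 and 0.0883). Adjusted over the list alone these counts were 6 and 7, and 0 and 8. Of 39 nitrogen catabolite repression genes, 5 (RSB1, OPT2, CAR2, PRB1 and UGA1) were higher, 20 lower and 14 did not pass, with 6 and 23 adjusted over the list alone (camera adjusted p = 2e-05, and adjusted p = 0.249 with an estimated correlation). The allantoate permease gene DAL5 was lower by 1.40 log2 units (-1.40 ± 0.11) and GAP1 differed by -1.20 ± 0.08. MEP2 differed by -0.34 ± 0.07, a call that ended without any single DMSO or rapamycin array (highest adjusted p = 0.17 without rapamycin replicate 2, range 0.012 to 0.17 over the alternatives). Of 20 genes of gluconeogenesis and the glyoxylate cycle, 0 were higher, 14 lower and 6 did not pass, with 15 lower adjusted over the list alone (camera adjusted p = 4.75e-08, and adjusted p = 0.249 with an estimated correlation). ADY2 differed by -1.53 ± 0.12. SFC1, a mitochondrial carrier gene, differed by -1.60 ± 0.28, a call that ended without either rapamycin array (highest adjusted p = 0.109 without replicate 2, range 0.00102 to 0.109). Of 41 genes of the respiratory chain and ATP synthase, 0 were higher, 20 lower and 21 did not pass, with 30 lower adjusted over the list alone (camera adjusted p = 3.92e-11, and adjusted p = 0.326 with an estimated correlation). SDH2 and QCR10 differed by -0.64 ± 0.11 and -0.57 ± 0.07, calls that ended without either rapamycin array (highest adjusted p = 0.122 without replicate 2 and 0.083 without replicate 1, ranges 0.00187 to 0.122 and 0.00289 to 0.083 over the alternatives). The hexose transporter list also holds MTH1, a regulator of these genes. Of its 19 genes, 0 were higher, 5 (HXT7, HXT4, MTH1, HXT5 and HXT2) lower and 14 did not pass, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.249 with an estimated correlation). HXT4 differed by -1.57 ± 0.07. The hexose transporter call ended without CID 3528206 replicate 2 (adjusted p = 0.0683, range 0.000218 to 0.249 over the alternatives) and without probe sets that can hybridise several genes, HXT7 among them (0.0605). For CIT2 the difference was -0.11 ± 0.07, with limma adjusted p = 0.275.

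Stress, chaperone and autophagy lists too were lower after the compound than after rapamycin. Of 66 genes of the general stress response, 0 were higher, 32 lower and 34 did not pass, with 42 lower adjusted over the list alone (camera adjusted p = 1.77e-13, and adjusted p = 0.249 with an estimated correlation). The small heat shock gene HSP26 differed by -1.37 ± 0.13 and CTT1 by -0.51 ± 0.11. Of 29 heat shock chaperones, 0 were higher, 9 lower and 20 did not pass, with 10 lower adjusted over the list alone (camera adjusted p = 0.00597, and adjusted p = 0.382 with an estimated correlation). SSA4, a heat-inducible chaperone, differed by -0.92 ± 0.07, and HSP26, SSA4 and 3 other genes are in both of these lists. Of 34 autophagy genes, 1 (ATG18) was higher, 8 lower and 25 did not pass, with 3 and 9 adjusted over the list alone (camera adjusted p = 0.00722, and adjusted p = 0.294 with an estimated correlation). ATG39, a receptor for autophagy of the nucleus, differed by -1.33 ± 0.10 and ATG8 by -0.70 ± 0.12. Of 37 proteasome genes, 1 (ECM29) was higher, 3 (RPN4, PRE3 and UFD1) lower and 33 did not pass, and 0 passed adjusted over the list alone (camera adjusted p = 0.000421, and adjusted p = 0.483 with an estimated correlation). Without CID 3528206 replicate 2 the chaperone and autophagy calls ended (adjusted p = 0.0807 and 0.0571, ranges 0.000239 to 0.382 and 0.000369 to 0.294 over the alternatives). The call for ATG8 ended without either rapamycin array, those for CTT1 and RPN4 without any single DMSO or rapamycin array, and that for PRE3 also without CID 3528206 replicate 1 (0.0715). Adjusted p was highest without rapamycin replicate 2, at 0.113 for ATG8, 0.178 for CTT1, 0.154 for RPN4 and 0.264 for PRE3 (ranges 0.000854 to 0.113, 0.0186 to 0.178, 0.00264 to 0.154 and 0.00667 to 0.264).

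Several translation lists were higher after the compound than after rapamycin, although most of their genes did not pass, and mitochondrial ribosomal proteins were lower. The ribosome biogenesis list did not pass, with 3 of 131 genes higher and 4 lower. Of 128 cytosolic ribosomal protein genes, 36 were higher, 0 lower and 92 did not pass, with 55 higher adjusted over the list alone (camera adjusted p = 3.07e-16, and adjusted p = 0.383 with an estimated correlation). RPL9A was higher by 0.95 ± 0.08 and RPS22A by 0.61 ± 0.10, the latter a call that ended without rapamycin replicate 2 (adjusted p = 0.0953, range 0.00375 to 0.0953). Of 72 mitochondrial ribosomal protein genes, 0 were higher, 10 lower and 62 did not pass, with 9 lower adjusted over the list alone (camera adjusted p = 2.01e-06, and adjusted p = 0.54 with an estimated correlation). MRP8 differed by -0.60 ± 0.07 and MRPL27 by -0.46 ± 0.09. Of 34 translation factors, 5 (GCD1, TIF4631, TIF4632, TEF4 and GCD7) were higher, 0 lower and 29 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.249 with an estimated correlation). Calls for GCD1 and TIF4631 ended without rapamycin replicate 1 (adjusted p = 0.119 and 0.116) or replicate 2 (0.0832 and 0.127, ranges 0.00642 to 0.119 and 0.00226 to 0.127). Of 19 aminoacyl-tRNA synthetases, 6 were higher, 0 lower and 13 did not pass, with 8 higher adjusted over the list alone (camera adjusted p = 6.96e-05, and adjusted p = 0.294 with an estimated correlation). The genes for the leucine and methionine enzymes, CDC60 and MES1, were higher by 0.56 ± 0.13 and 0.47 ± 0.09. Of 24 unfolded protein response genes, 9 were higher, 1 (ERV2) lower and 14 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0309, and adjusted p = 0.383 with an estimated correlation). EUG1, a disulfide isomerase gene, was higher by 0.81 ± 0.14 and the chaperone gene LHS1 by 0.80 ± 0.09, the latter a call that ended without rapamycin replicate 2 (adjusted p = 0.0595, range 0.000876 to 0.0595). Calls for MRP8 and EUG1 ended without either rapamycin array, and those for CDC60, MES1 and MRPL27 without any single DMSO or rapamycin array. Without rapamycin replicate 2 adjusted p was 0.152 for MES1 and 0.161 for MRPL27 (ranges 0.00177 to 0.152 and 0.00197 to 0.161). The highest adjusted p was 0.0719 for MRP8 without rapamycin replicate 1, and 0.198 for CDC60 and 0.117 for EUG1 without rapamycin replicate 2 (ranges 0.00174 to 0.0719, 0.00145 to 0.198 and 0.002 to 0.117 over the alternatives). The list calls for translation factors and the unfolded protein response ended without CID 3528206 replicate 2 (adjusted p = 0.0767 and 0.104, ranges 0.00499 to 0.249 and 0.0109 to 0.383), the latter also without rapamycin replicate 1 (0.0642) and without the third of genes with the lowest mean (0.0875).

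Drug transport, iron and sterol lists were higher after the compound than after rapamycin. Against DMSO, the iron list passed after the compound, while the multidrug and ergosterol lists did not (camera adjusted p = 0.116 and 0.0844). Of 28 multidrug resistance regulon genes, 8 were higher, 2 (RPN4 and AQR1) lower and 18 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.294 with an estimated correlation). The drug pump genes PDR10 and PDR5 were higher by 1.09 ± 0.10 and 0.71 ± 0.08. Against DMSO, PDR5 fell by 0.53 ± 0.08 after rapamycin, and its difference of 0.18 ± 0.08 after the compound did not pass. Of 34 iron regulon genes, 13 were higher, 0 lower and 21 did not pass, with 15 higher adjusted over the list alone (camera adjusted p = 6.82e-05, and adjusted p = 0.249 with an estimated correlation). ARN2, a siderophore transporter gene, was higher by 1.08 ± 0.11. Of 30 ergosterol biosynthesis genes, 6 were higher, 1 (ERG28) lower and 23 did not pass, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.00667, and adjusted p = 0.281 with an estimated correlation). The sterol importer gene AUS1 and the HMG-CoA reductase gene HMG1 were higher by 0.86 ± 0.18 and 0.81 ± 0.13. Calls for PDR5, AUS1 and HMG1 ended without either rapamycin array, and that for AUS1 also without either DMSO array (0.0505). Adjusted p was highest without rapamycin replicate 2, at 0.0653, 0.16 and 0.106 (ranges 0.00126 to 0.0653, 0.00209 to 0.16 and 0.000819 to 0.106 over the alternatives). The multidrug call ended without the third of genes with the lowest mean (0.0577, range 2.67e-05 to 0.294).

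Cell cycle lists also differed between the treatments. Of 38 G1/S genes, 9 were higher after the compound, 1 (CLN1) lower and 28 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.00433, and adjusted p = 0.249 with an estimated correlation). CDC9 was higher by 0.87 ± 0.07 and the mismatch repair gene MSH6 by 0.56 ± 0.10. Of 27 G2/M genes, 0 were higher, 14 lower and 13 did not pass, with 16 lower adjusted over the list alone (camera adjusted p = 2.01e-06, and adjusted p = 0.249 with an estimated correlation). The cell wall sensor gene WSC4 and the cytokinesis gene HOF1 differed by -0.96 ± 0.11 and -0.74 ± 0.17. Of 25 genes of M/G1 and daughter cells, 0 were higher, 10 lower and 15 did not pass, with 1 and 12 adjusted over the list alone (camera adjusted p = 0.00024, and adjusted p = 0.249 with an estimated correlation). PRY3 differed by -0.90 ± 0.09 and SIC1, an inhibitor of the cyclin-dependent kinase, by -0.76 ± 0.12. Of 9 histone genes, 0 were higher, 3 (HHT1, HHO1 and HHT2) lower and 6 did not pass, with 6 lower adjusted over the list alone (camera adjusted p = 0.00167, and adjusted p = 0.483 with an estimated correlation). Of 26 pheromone response genes, 0 were higher, 7 lower and 19 did not pass, with 1 and 9 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.249 with an estimated correlation). CIK1, a motor-associated protein gene, differed by -0.45 ± 0.08 and STE2 by -0.42 ± 0.10. The call for WSC4 ended without rapamycin replicate 1 (adjusted p = 0.0547, range 0.000791 to 0.0547 over the alternatives) and that for PRY3 without rapamycin replicate 2 (0.0517, range 0.00141 to 0.0517). Calls for HOF1, HHT1, HHO1 and CIK1 ended without any single DMSO or rapamycin array. Their highest adjusted p was 0.175, 0.126 and 0.162 without rapamycin replicate 1 and 0.128 without rapamycin replicate 2 (ranges 0.00108 to 0.175, 0.00218 to 0.126, 0.00343 to 0.162 and 0.00306 to 0.128). Calls for MSH6 and SIC1 ended without either rapamycin array, and that for STE2 without any single DMSO or rapamycin array or CID 3528206 replicate 1 (0.0523). Without rapamycin replicate 2 their adjusted p was 0.126, 0.105 and 0.244 (ranges 0.00317 to 0.126, 0.000876 to 0.105 and 0.0201 to 0.244). The pheromone list call ended without CID 3528206 replicate 2 (adjusted p = 0.193, range 0.00161 to 0.249). Without the third of genes with the lowest mean the pheromone call (0.0875) and the G1/S call (0.0577, range 0.00079 to 0.249) ended.

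Between the compound and rapamycin limma called 1022 genes, 508 higher and 514 lower, and 63 at least 2-fold, 25 higher and 38 lower. The arrays did not overlap for any of the 1022, as for 3460 of all genes tested, where chance gives 33.3%. Of the 1022, the mean after the compound lay between those of DMSO and rapamycin for 471, further from DMSO than rapamycin for 223 and on the other side of DMSO for 328. Camera called 21 of 38 lists, 8 up and 13 down, and 7 lists passed in no comparison: Gcn4-linked amino acid synthesis, methionine and sulfate assimilation, RNA polymerases I and III, glycolysis, the phosphate and zinc regulons and oxidative stress (lowest camera adjusted p 0.104). Called against DMSO but not between the treatments were the retrograde response, ribosome biogenesis, vacuolar hydrolases, the TCA cycle, cell wall integrity, sporulation, both cell type lists, TOR components and amino acid permeases (0.0883 to 0.826). The count of genes depended on single arrays, with 105 and 96 without rapamycin replicate 1 and 2, 397 without either DMSO array or with the 4 arrays alone, 1300 without CID 3528206 replicate 1 and 2646 without CID 3528206 replicate 2. It was 428 when all probe sets were tested and 1888 with the difference between 3' and 5' control probe sets as a covariate, chosen after seeing the data, and the 2-fold count was 32 without the third of genes with the lowest mean and 116 without CID 3528206 replicate 2. The DMSO arrays are not part of this comparison, and leaving out either gave the same fit as the 4 arrays alone. A call between the treatments that ended without a DMSO array therefore reflects the change of the pooled spread, not that array. With the 4 arrays alone the calls for MRPL27, CDC60, MES1, RPN4, PRE3, AUS1, HHT1, HHO1, HOF1, CIK1, STE2, MEP2, CTT1 and MET17 ended (adjusted p 0.0505 to 0.103), and with all probe sets tested those of the same genes except HHT1 (0.0508 to 0.117). Calls for PRE3 and HOF1 ended after quantile normalization (both 0.0529) and that for STE2 with a variance prior with trend and robust fitting (0.0542).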

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

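Tests of the marker genes, of the weight of CID 3528206 replicate 1 on the list calls and of RNA breakdown were chosen after the results were seen. So were the count of genes changed against DMSO in the test of a weaker response and the single probe sets described. The others were set before, although the covariate used for the ribosome biogenesis list was chosen after the data were seen.

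Probe sets that name no gene in the probe table gave signal outside the genes compared. Of 3470 such probe sets, 30 changed at least 2-fold after rapamycin (17 up, 13 down) and 25 after CID 3528206 (14 up, 11 down) by limma, while 0 of 1746 S. pombe probe sets did. At any size of change 220 and 174 were called, but so were 75 and 43 of the S. pombe probe sets. The largest rise after rapamycin was of 1770587_at, by 4.64 ± 0.20 (limma adjusted p = 2.51e-05), and it rose by 2.99 ± 0.20 after the compound, while 1779784_at rose by 3.96 ± 0.09 and by 3.73 ± 0.09. What these probe sets measure is not given in the sources used here, and no explanation was tested.

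Genes deleted in BY4741 and alpha-cell genes were measured in every array. Unspecific background is argued against, since the lowest of the 4 deleted genes and 3 URA3 control probe sets lay 4.28 log2 units above the highest S. pombe 99th percentile. An exchange of single samples is argued against too, since all 6 arrays showed MET17, LEU2, URA3 and STE3 more than 1 unit above it. Cells of a strain other than BY4741 may be the source, since 7 of 7 genes tested lay above the percentile in both DMSO arrays, though this was found from the same values. Marker genes carried on a plasmid stay open for the deleted genes and were not tested, and no biological explanation was tested.

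CID 3528206 replicate 1 had the largest difference between 3' and 5' control probe sets, in the group set against rapamycin. Breakdown of the yeast RNA before labelling is argued against as the only source. The bacterial control RNAs exceeded the mean of the other 5 arrays by 1.23 log2 units and the yeast genes by 0.66, with ranges among those arrays of 0.31 and 0.23. Breakdown of yeast RNA in addition to an effect on both kinds of RNA stays open, since this test cannot separate them. The bias of that array as the whole cause of the list differences is argued against, since 21 of 21 lists kept their direction and passed without it. Of the differing genes, 53.9% had a mean outside the interval from DMSO to rapamycin, and 35.4% also changed against DMSO after the compound. A weaker form of the rapamycin response is argued against for these 35.4% (223 further from DMSO and 139 on its other side). For the 223, the change against DMSO followed from their position, so only their difference from rapamycin counts here. The set of differing genes itself depended on single arrays. A weaker response stays open for the rest and the 471 inside. A different action of the 2 compounds, which the design names, stays open as untested.

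The ribosome biogenesis list was higher after rapamycin (median 0.23, mean 0.19) while ribosomal protein genes fell. With the difference between 3' and 5' control probe sets as a covariate, the list mean was 0.22. That difference averaged 1.072 and 0.91 over yeast genes in the DMSO arrays and 1.139 and 0.995 in the rapamycin arrays. Because these values overlap, the covariate could hardly move the list mean, so this fit cannot decide on uneven 3' signal. A fall of total messenger RNA hidden by the normalization cannot be told apart. The bacterial poly-A control probe sets differed by -0.06 between rapamycin and DMSO, smaller than the list median, but the 2 DMSO arrays differed in them by 0.36, more than that median, so the limit set for this test was too narrow to decide. The rapamycin treatment itself stays open as untested.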

How the results depend on the processing

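The covariate for the difference between 3' and 5' control probe sets and the fits with separate DMSO arrays were chosen after the data were seen, and the other alternatives were chosen before. Of the counts, correlations and numbers of lists that answer the comparisons, 168 values under the 22 alternatives stayed within the set limits and 29 moved. These limits were wide. A count of 3698 genes changed after rapamycin with the 4 arrays alone, against 2873 in the main fit, counted as within them. Staying within the limits therefore does not mean that a count was stable. Gene lists kept direction and side of the threshold in 1998 cases, were no longer past it in 104 and newly past it in 55. For named genes these were 2869, 156 and 40, and 0 results reversed. The main fit pooled the spread of the 3 groups. The standard deviation of the difference between replicates was 0.267 log2 units for CID 3528206, 0.123 for DMSO and 0.122 for rapamycin. Standard errors may therefore be too small for comparisons with CID 3528206 and too large for rapamycin against DMSO. Leaving out 1 array leaves a lone array in its group, assumed to vary like the other groups, which these spreads contradict for CID 3528206. In every such run 118 of 163 gene calls and 47 of 59 list calls were kept.

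Over the 6 runs without 1 array, genes changed ranged from 1794 to 3698 after rapamycin, from 1553 to 3552 after CID 3528206 and from 96 to 2646 between them. The 2-fold count between the treatments ranged from 55 to 116, the correlation of log2 differences from 0.818 to 0.898 and the genes changed in the same direction by both from 1171 to 2536. Fewer residual degrees of freedom go with each run, but they cannot account for the counts that rose without a CID 3528206 array. Leaving out such an array takes the wider spread between the CID 3528206 replicates (standard deviation 0.267, against 0.123 and 0.122) out of the pooled spread. The 4 arrays of rapamycin and DMSO alone also gave 3698 genes. Beyond this the cause was not tested. At an adjusted p under 0.01 the genes changed were 1872, 1706 and 214, by construction. Without the third of genes with the lowest mean the 2-fold counts were 263, 224 and 32, with fewer genes tested. With an estimated correlation camera called 0, 0 and 0 lists. Between the treatments, 397 genes changed with the 4 arrays alone, 428 with all probe sets tested and 1888 with the covariate, and the cause was not tested.

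With a separate DMSO array for each treatment, 1169 and 1158 genes changed in the same direction, with a lone control array assumed to vary like the other groups, while r was 0.844 and 0.877. Fry did not call ribosome biogenesis (0.224), the proteasome (0.0574) or the respiratory chain (0.0696) after CID 3528206, nor mitochondrial ribosomal proteins (0.0856) or the proteasome (0.0596) between the treatments.

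After quantile normalization of the tested genes, 11 genes called after rapamycin changed sign. With the mean of the probe sets of a gene, 1 called gene changed sign in each comparison with DMSO. With the replicate number as a block, the genes changed were 3195, 3082 and 1510, and deviations of replicates from their group mean correlated by 0.25, 0.43 and 0.32 between pairs of groups. Signal over background limits the lowest genes: 98.6% of genes had a mean above the background.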

Other observations

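The purine and carnitine lists were drawn up after the largest changes were seen, with the genes that prompted them left out of their tests, and the single genes below were chosen after their values were seen.

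Purine and one-carbon genes were among the largest falls. SHM2, a serine hydroxymethyltransferase gene, fell by 2.81 ± 0.08 after rapamycin, and GCV2 of glycine cleavage fell by 2.49 ± 0.15. The purine synthesis genes ADE17 and ADE2 fell by 2.61 ± 0.15 and fell by 2.33 ± 0.10. After CID 3528206 the falls of SHM2, GCV2 and ADE2 were -2.05 ± 0.08, -2.26 ± 0.15 and -1.59 ± 0.10. The activator gene BAS1 rose by 1.12 ± 0.08 after rapamycin. Some genes of carnitine and fatty acid metabolism rose, with YAT2 up by 4.12 ± 0.07, YAT1 by 2.44 ± 0.10 and the carnitine acetyltransferase gene CAT2 by 2.37 ± 0.07 after rapamycin. The peroxisomal genes POT1 and POX1 rose by 2.20 ± 0.10 and 2.12 ± 0.09.

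Some genes changed in opposite directions after the 2 treatments. ISF1 rose by 0.97 ± 0.12 after rapamycin and fell by 0.69 ± 0.12 after the compound, and TMA10 rose by 0.72 ± 0.18 and fell by 0.96 ± 0.18. EEB1, an ester synthesis gene, fell by 0.75 ± 0.07 after rapamycin and rose by 0.46 ± 0.07 after the compound. The mean of 17 probe sets for ribosomal RNA was 0.71 log2 units lower after rapamycin (-0.71) and differed by -0.61 after the compound, not tested here. These are signals after labelling with a 3' in vitro transcription kit, and the amount of ribosomal RNA was not measured.

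A fall of much of the purine and one-carbon pathway may be part of the response to rapamycin. Of the 23 members that had not prompted the list, 4 rose and 12 fell (camera adjusted p = 0.00731 over the 2 lists, and p = 0.107 with an estimated correlation). After CID 3528206, 4 rose and 12 fell (camera adjusted p = 0.0165, and p = 0.124 with an estimated correlation).

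A rise of part of the carnitine and fatty acid pathway may be part of it too. Of 24 remaining members, 9 rose and 2 (ECI1 and PXA1) fell after rapamycin, with a median of 0.163 (camera adjusted p = 0.00731, and p = 0.0588 with an estimated correlation). The mean was 0.491, and these members still include CAT2, POT1 and POX1, the large rises named above. The camera result therefore rests in part on genes already seen to be high. After CID 3528206, 10 rose and 4 fell, and the list did not pass (camera adjusted p = 0.0773). Members such as FOX2 of peroxisomal oxidation did not pass, with a difference of -0.12 ± 0.07 after rapamycin.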
